A study of Mus musculus with 6 samples.

How the data were processed

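RNA sequencing of liver was analysed for 6 C57BL/6 mice, an inbred laboratory strain, 3 per diet. Groups and replicate numbers were taken from the sample labels. The labels name the diets CSAA, the control feed, and CDAA. In this field the abbreviations stand for choline-supplemented and choline-deficient amino acid-defined feed. Per the labels' protocols and the series' design text, the mice were 6 weeks old at the start, had 1 week to acclimatise, and those assigned to CDAA then passed through a mixed feed over 1 week and were sampled at week 6 after it. Each library started from 3 ug of RNA.

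Each deposited file holds 1 library with 21899 genes and 2 value columns. The first column holds whole-number read counts per gene, per the file headers, not normalised by the authors. The second holds FPKM, per the file headers, which for every gene in every library equalled the count scaled by the listed gene length and the library total, within a relative tolerance of 0.001. FPKM was checked in this way and otherwise not used. Per the submitters' processing notes, the tools include cutadapt 1.15, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0, and the builds mm10 and mm9 are both named. The role of each tool, the strand setting and the treatment of reads with several matches are not given in the sources used here. Genes of multigene families such as Mup, Cyp2c, Cyp4a12, Orm, Saa and Serpina1 are therefore uncertain where reads could be split between near-identical copies, and the same holds for overlapping genes.

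Of the gene identifiers, 21846 are in GENCODE M21, and 21807 of these are protein coding there. Start and end matched that annotation, on GRCm38, for 562 genes and differed for 21284. The headers name no build, so coordinates are printed as the files give them, with the build unnamed, and none is taken from the reference. A symbol was shared by more than 1 identifier for 20 symbols covering 42 identifiers. No row lacked a gene identifier.

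Library totals ran from 14580676 to 17367173 reads. A count of 3 corresponds to 0.173 CPM (reads of a gene scaled to a common library total) at the highest total and to 0.206 CPM at the lowest. Such limits cover counting error only, because the reads carry no molecular identifiers as far as the labels say.

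Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, glmQLFit and glmQLFTest), for CDAA against CSAA with no further covariate. P-values were adjusted by the Benjamini-Hochberg method over the 12845 genes kept, and a gene passed at an adjusted p under 0.05. The standard error of a log2 fold change was obtained as its size over the square root of the F statistic. Levels are CPM on TMM-scaled library sizes unless said otherwise. TMM factors were 1.17, 1.10 and 1.04 for CSAA replicates 1 to 3 and 0.904, 0.883 and 0.935 for CDAA replicates 1 to 3. Without these factors the median log2 fold change of all tested genes moved by -0.28, so every change below is relative to the TMM scale.

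Before the data were examined, 41 gene lists with 918 entries were written from general knowledge of liver, of which 17 entries had no match in the files and 2 were matched through another symbol of the same RefSeq gene. For each list the passing members were counted over all genes tested and adjusted over the list alone. Lists with at least 3 tested members (39 lists) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Genes named in the text were also fixed by rule beforehand. The rule took the 6 largest rises and 6 largest falls among passing genes with a mean of at least 10 CPM in the higher group and no overlap between the groups. It added up to 4 passing members of the lipid droplet list each way by smallest adjusted p, then Plin2, Cidec, Plin5, Hsd17b13 and Pnpla3 whatever their result. From every other list it took the 2 members with the smallest adjusted p in the direction more passing members had. A gene chosen by the rule is counted even where the text does not name it. Any other gene named was chosen after its values were seen.

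The same functions were tested on simulated counts for 12845 genes with the real means, library sizes and dispersion, in which 200 genes were changed. At a change of 1.5-fold 2 of 67 were recovered, at 2-fold 33 of 67 and at 4-fold 61 of 66. In that simulation 10 unchanged genes were called, and 0 genes were called when none was changed. Changes well under 2-fold were thus mostly missed in that simulation, where 200 of 12845 genes were changed. In the libraries 14.8% of tested genes were called. The adjusted p depends on that share, so recovery in the libraries can differ from the simulated one. There the genes called higher had a median log2 fold change of 0.58.

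Alternatives fixed beforehand were RLE factors computed in edgeR, library size only, upper-quartile factors, no filter beyond a total above 0, and a mean of at least 1 CPM. Also fixed were DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, each replicate left out in turn, and the replicate number as a block. Thinning all libraries to the lowest total, leaving out the pancreatic and muscle genes, and list counts without single libraries were added after the data were seen. Alternatives for files without counts did not apply. No pair of libraries was a duplicate: the chi-square statistic per degree of freedom within a group was at least 24.8. Python 3.11.15 and matplotlib 3.10.9 drew the plots.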

Results

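Liver RNA was sequenced from 6 C57BL/6 mice, 3 labelled CSAA (the control feed) and 3 labelled CDAA (the choline-deficient counterpart). The mice on CDAA were changed to it through a mixed feed over 1 week, and all livers were taken at week 6 after that. The stated purpose was to examine transcripts of proteins located on lipid droplets, the organelles in which hepatocytes store neutral lipid. The libraries labelled CSAA held 17367173, 17080811 and 15459290 reads over genes. Those labelled CDAA held 14580676, 15291743 and 15053526. Between 14565 and 15416 genes had at least 1 read. Groups are called by their labels throughout, because the files hold no transcript that marks the feed itself.

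All 6 libraries correlated best with a library of their own group. Pearson correlations of log2 CPM across genes ran from 0.961 to 0.980 within groups and from 0.929 to 0.957 between them. The first principal component, with 58.1% of the variance, separated the groups, and the second, with 17.6%, set CDAA replicate 3 (-45.6) apart from CDAA replicate 1 (29.6) and replicate 2 (7.23). Mitochondrially encoded transcripts took 4.68 ± 0.565% of reads in CSAA and 6.01 ± 0.456% in CDAA (mean ± SD, n = 3 each, exact two-sided permutation p = 0.1). The 10 most abundant genes took 16.4 ± 0.920% and 18.5 ± 0.314% (n = 3 each, exact permutation p = 0.1). With 3 against 3 libraries 0.1 is the smallest p such a test can give. Y-linked Ddx3y, Kdm5d, Uty and Eif2s3y were present in all 6 libraries, with Ddx3y between 73.1 and 98.6 CPM on unscaled totals, and 0 of the 4 passed the test between groups. CDAA replicate 1 also held transcripts of other tissues. Its 18 pancreatic acinar genes summed to 2136 CPM, against at most 16.9 CPM in any other library, and its 12 striated muscle genes to 280.4 CPM, against at most 1.61 CPM.

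**Figure D1:**
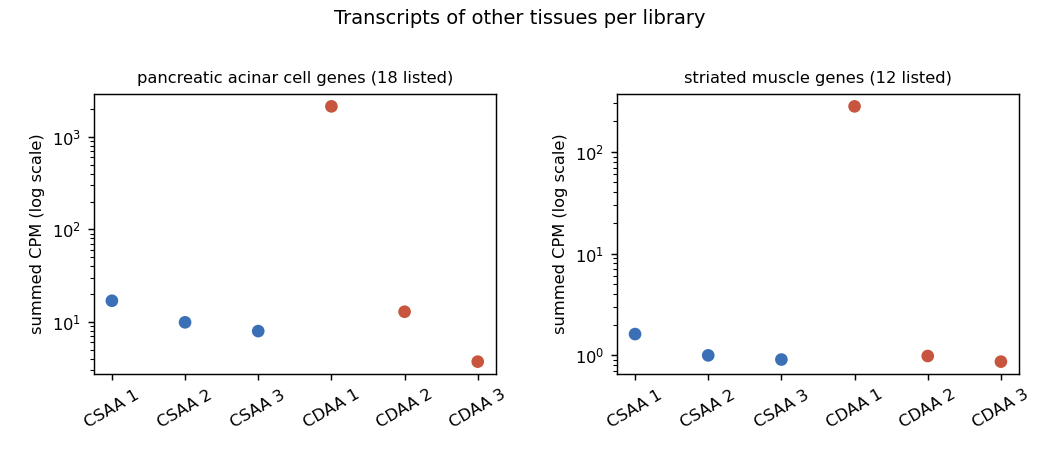
Summed CPM on unscaled totals (log axis) of 18 pancreatic acinar genes (left) and 12 striated muscle genes (right), 1 point per library, blue for CSAA and red for CDAA. CDAA replicate 1 stands at 2136 and 280.4 CPM, and the other 5 libraries lie at or below 16.9 and 1.61 CPM.

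The comparison of the diets found more genes lower than higher in the libraries labelled CDAA. Of 12845 genes tested, 1355 were lower and 546 higher at an edgeR adjusted p under 0.05, and 930 of the former and 97 of the latter changed at least 2-fold. Of the genes with the 6 largest falls, Mmp12, Gpnmb and Atp6v0d2 are in the list of lipid-associated macrophage genes and Lcn2 is in the acute phase and neutrophil lists, while Acod1 and Vmn2r3 are in none. Mmp12, the macrophage elastase, fell from 126.1 ± 100.1 to 0.143 ± 0.188 CPM (mean ± SD, n = 3 each), a log2 fold change of -9.67 ± 0.92 (SE, edgeR adjusted p = 0.00139). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, fell from 156.7 ± 137.4 to 1.35 ± 0.819 CPM (log2 -6.85 ± 0.77, edgeR adjusted p = 0.00192). Lcn2, an iron-binding acute phase protein, fell from 117.7 ± 54.5 to 2.27 ± 1.79 CPM (log2 -5.70 ± 0.58, edgeR adjusted p = 0.00155). Acod1, which makes itaconate in activated macrophages, had a log2 fold change of -6.38 ± 0.66, and Atp6v0d2, a proton pump subunit, one of -4.68 ± 0.56. Vmn2r3, a vomeronasal receptor gene, had a log2 fold change of -4.38 ± 1.23 (edgeR adjusted p = 0.0496) that rested on 27.9 CPM in CSAA replicate 1, against 2.72 and 3.11 CPM in CSAA replicates 2 and 3. Single libraries also moved the size of other falls. Gpnmb was at 315.3 CPM in CSAA replicate 1 and at 75.2 and 79.5 in CSAA replicates 2 and 3. Its log2 fold change was -5.81 without CSAA replicate 1 and -7.46 without CDAA replicate 2. Mmp12 was at 240.9 CPM in CSAA replicate 1 and at 56.9 and 80.6 in CSAA replicates 2 and 3, and its log2 fold change was -8.77 without the former. In CDAA, Mmp12 was at 0.356 CPM in replicate 3 and at 0 and 0.0741 in replicates 1 and 2, and Acod1 at 0.213 CPM in replicate 3 and at 0.0761 and 0.0741 in replicates 1 and 2. Without CDAA replicate 3 the fitted log2 fold changes were -11.45 for Mmp12 and -7.03 for Acod1, which rest on 1 and 2 reads left in CDAA. The ratios of read rates, CSAA over CDAA, were then 3501 for Mmp12 (95% exact counting interval 628.2 to 138300) and 144.4 for Acod1 (39.8 to 1195). The log2 fold change of Lcn2 was -6.56 without CDAA replicate 1. That of Vmn2r3 was -2.42 without CSAA replicate 1 and -6.17 without CDAA replicate 3.

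Of the genes with the 6 largest rises, Serpina1e and Hsd3b5 are in the list of male-biased liver genes and Cyp2c40 is in the female-biased list, while Mup18, Adgrf1 and Pitx3 are in none. Cyp2c40, a cytochrome P450, rose from 0.203 ± 0.310 to 16.1 ± 6.02 CPM (log2 6.39 ± 0.72, edgeR adjusted p = 0.00197). Serpina1e, an alpha-1-antitrypsin gene, rose from 776.9 ± 235.9 to 5107 ± 3510 CPM (log2 2.72 ± 0.57), with 1481 CPM in CDAA replicate 3 against 8488 and 5352 in CDAA replicates 1 and 2. Mup18, a major urinary protein gene, rose by 2.86 ± 0.53, the steroid dehydrogenase gene Hsd3b5 by 2.38 ± 0.54, the receptor gene Adgrf1 by 2.74 ± 0.54 and the homeobox gene Pitx3 by 2.48 ± 0.55 on the log2 scale. Cyp2c40, Mup18 and Serpina1e belong to families of near-identical genes, so their reads could be split between copies. Pitx3 (chromosome 19, from 46124124, minus strand) overlaps the end of Elovl3 (to 46124133, plus strand), which also rose (log2 2.04 ± 0.31). The strand setting is not given, and whether reads of Elovl3 were counted for Pitx3 was not tested. In the files, Mmp12 (ENSMUSG00000049723) lies on chromosome 9 from 7344381 to 7369499, Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49013480 to 49047863, and Cyp2c40 (ENSMUSG00000025004) on chromosome 19 from 39755515 to 39801258. The headers do not name the build, and most coordinates differ from GRCm38. In CSAA, Cyp2c40 was at 0.559 CPM in replicate 3 and at 0.0492 and 0 in replicates 1 and 2. Without CSAA replicate 3 the fitted log2 fold change of Cyp2c40 was 8.93, with 1 read left in CSAA and a ratio of read rates, CDAA over CSAA, of 640.3 (95% exact counting interval 114.5 to 25330). In the same fit it was 3.69 for Adgrf1 and 3.13 for Hsd3b5.

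The size of these counts depended on the scaling and on single libraries. Of the 1901 called genes 0 changed sign in any alternative fit. That says little, since 1898 of them had no overlap between the groups. With library size only, 137 genes were higher and 2745 lower (4.75% higher and 95.3% lower, against 28.7% and 71.3% with TMM). Without CSAA replicate 1, 2 or 3 or CDAA replicate 1, 2 or 3, in that order, 76, 163, 396, 223, 157 and 688 genes were higher and 568, 859, 856, 950, 757 and 1456 lower. Of the 79 passing genes chosen by the naming rule, 50 passed in all 6 of these fits and 29 did not. Mup18 did not pass without CSAA replicates 1 or 2 (highest edgeR adjusted p = 0.0559). Adgrf1 did not pass without CSAA replicate 1 (highest edgeR adjusted p = 0.0675). Serpina1e did not pass without CSAA replicates 1 or 2 or CDAA replicate 2 (highest edgeR adjusted p = 0.0863). Pitx3 did not pass without CSAA replicates 1 or 3 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.0614). Hsd3b5 did not pass without CSAA replicates 1 or 2 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.0922). Vmn2r3 did not pass without CSAA replicates 1, 2 or 3 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.188). Mmp12, Gpnmb, Lcn2, Acod1, Atp6v0d2 and Cyp2c40 passed in all 6 such fits. No overlap between the groups was seen for 36.1% of tested genes, where chance gives 10%. Of 39 gene lists tested with camera at the preset correlation, 12 passed as higher, 16 as lower and 11 did not pass. With an estimated correlation 0 of these 28 calls held, and 8 lists were at an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way on balance, called 22 lists.

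**Figure D2:**
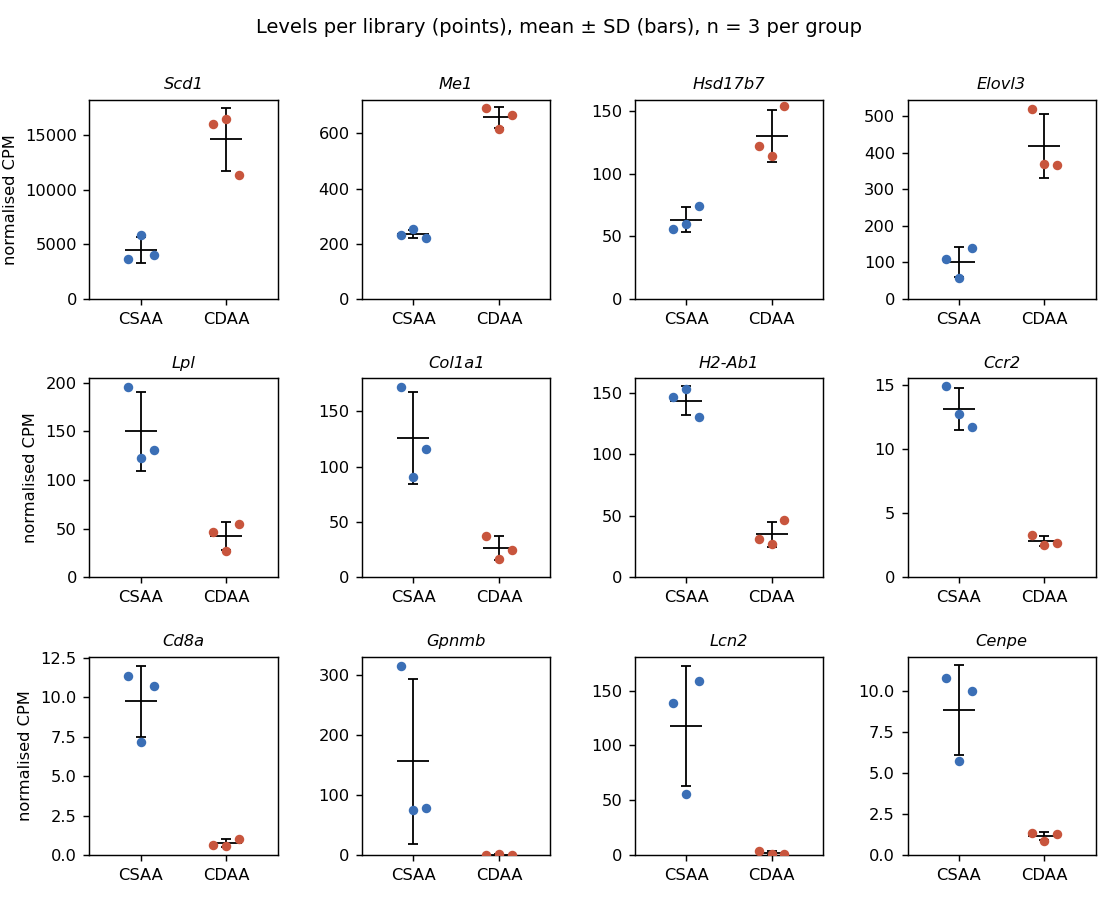
Normalised CPM of 12 genes picked from the 88 chosen by the naming rule, 1 point per library, with mean ± SD as bars and n = 3 per group, blue for CSAA and red for CDAA. All 12 passed in all 6 fits with 1 library left out, whereas 29 of the 79 passing genes of the rule did not. The rule took these genes by their test results in the same libraries, so the separation shown is no independent result. The lipid synthesis genes Scd1 and Me1 lie higher in all 3 libraries labelled CDAA, and Gpnmb, Lcn2 and Cd8a lie higher in all 3 labelled CSAA.

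Genes of lipid droplet proteins moved both ways. Of 49 tested members, 11 were higher in the libraries labelled CDAA, 3 lower and 35 did not pass, and adjusted over the list alone 13 were higher and 3 lower. Among the members that rose, those with the smallest adjusted p were sterol synthesis enzymes also found on droplets. Lss, lanosterol synthase, rose from 53.6 ± 0.927 to 95.6 ± 12.4 CPM (log2 0.84 ± 0.11, edgeR adjusted p = 0.00369). Hsd17b7 rose from 63.4 ± 9.96 to 130.3 ± 21.02 CPM (log2 1.04 ± 0.16, edgeR adjusted p = 0.00541), Nsdhl by 1.23 ± 0.20 and Sqle, squalene epoxidase, by 1.04 ± 0.22 on the log2 scale. Pnpla3, a droplet lipase gene induced by lipid synthesis, rose from 2.39 ± 1.22 to 12.2 ± 7.80 CPM (log2 2.35 ± 0.57, edgeR adjusted p = 0.0313). Cidec, which promotes droplet fusion, fell from 13.4 ± 5.64 to 5.87 ± 0.985 CPM (log2 -1.19 ± 0.32, edgeR adjusted p = 0.0428). The lysophospholipid acyltransferase genes Lpcat2 (log2 -2.02 ± 0.37) and Lpcat1 (log2 -0.93 ± 0.24) also fell. Plin2, the main droplet coat protein of hepatocytes, was at 681.9 ± 31.3 CPM in CSAA and 870.1 ± 81.5 CPM in CDAA and did not pass (log2 0.35 ± 0.12, edgeR adjusted p = 0.0981). Plin5 (log2 0.05 ± 0.20) and Hsd17b13 (log2 -0.29 ± 0.15) did not pass either (edgeR adjusted p = 0.909 and 0.239). The other members that rose, Acsl1, Cav1, Abhd5, Gpat4, Ldah and Vps13c, were named after their values were seen. Plin2 (ENSMUSG00000028494) lies on chromosome 4 from 86566623 to 86588297 and Cidec (ENSMUSG00000030278) on chromosome 6 from 113401595 to 113412721, in the files' unnamed build.

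As a set, the lipid droplet list had a median log2 fold change of 0.19 (camera adjusted p = 0.000391 at the preset correlation, adjusted p = 0.219 with an estimated correlation). Of its members 14 are shared with other lists, and Lss, Hsd17b7, Nsdhl and Sqle are also in the cholesterol synthesis list. Without shared genes the median was 0.15 (camera adjusted p = 0.0126 at the preset correlation). On library size only, the median was -0.09. Without CSAA replicate 1, 2 or 3 or CDAA replicate 1, 2 or 3, in that order, 4, 4, 5, 5, 5 and 13 members were higher and 1, 1, 2, 1, 1 and 3 lower. Sqle did not pass without CSAA replicates 2 or 3 or CDAA replicate 1 (highest edgeR adjusted p = 0.0746). Pnpla3 did not pass without CSAA replicates 1 or 3 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.119). Cidec did not pass without CSAA replicates 1 or 2 or CDAA replicates 1, 2 or 3 (highest edgeR adjusted p = 0.126). Lpcat1 did not pass without CSAA replicates 1, 2 or 3 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.148). Lss, Hsd17b7, Nsdhl and Lpcat2 passed in all 6 fits. In the same libraries the hepatocyte list had a median of 0.44 and the monocyte and macrophage list one of -1.79. The log2 fold change of Lpcat2 was -2.63 without CDAA replicate 3.

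**Figure D3:**
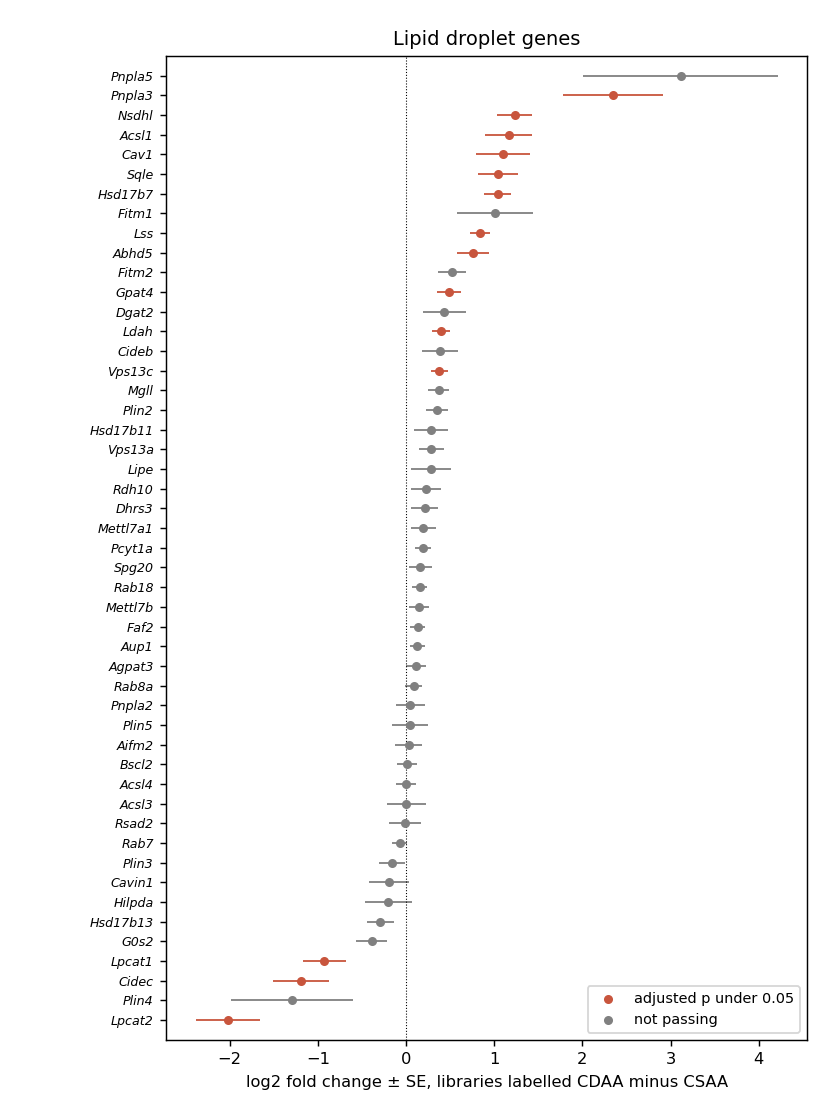
Log2 fold change (libraries labelled CDAA minus CSAA) ± SE of the 49 tested lipid droplet genes, from the edgeR fit on 3 libraries per group, with members at an adjusted p under 0.05 in red. 11 members lie above 0 and 3 below 0 among those passing, while Plin2 (0.35), Plin5 (0.05) and Hsd17b13 (-0.29) do not pass.

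Lipid synthesis genes were higher in the libraries labelled CDAA. Of 25 cholesterol synthesis genes 20 rose and 0 fell (21 higher adjusted over the list alone, median log2 0.87), among them Lss and Fdps, which makes farnesyl diphosphate (log2 1.36 ± 0.19, edgeR adjusted p = 0.00403). Of 22 genes of fatty acid and triglyceride synthesis 12 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.88). The gene that fell was Scd2, named after its value was seen. Scd1, the stearoyl-CoA desaturase, rose from 4491 ± 1179 to 14618 ± 2875 CPM (log2 1.70 ± 0.26, edgeR adjusted p = 0.00589). Me1, malic enzyme, a source of NADPH, rose from 235.4 ± 15.4 to 659.0 ± 38.2 CPM (log2 1.49 ± 0.12, edgeR adjusted p = 0.00121). Scd1 (ENSMUSG00000037071) lies on chromosome 19 from 44382894 to 44396318 and Me1 (ENSMUSG00000032418) on chromosome 9 from 86463424 to 86578006. The camera adjusted p was 6.41e-16 for the cholesterol list and 3.89e-10 for the fatty acid list, with adjusted p = 0.199 and 0.219 with an estimated correlation. Leaving out single libraries, in the order used above, gave 10, 10, 16, 15, 15 and 19 higher members of the cholesterol list and 3, 8, 7, 5, 6 and 15 of the fatty acid list. Lss, Fdps, Scd1 and Me1 passed in all 6 fits. The median of the fatty acid list was 1.08 without CDAA replicate 3. In that list 1 member was lower without CDAA replicate 1 or 3, and 0 were in the other 4 fits.

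Genes of lipid export, bile acids and oxidation tended to positive fold changes with few passing members. The 20 hepatocyte markers had a median of 0.44 in the same libraries, so the medians below are not set apart from that of hepatocyte transcripts in general. A difference from that list was not tested. Of 18 lipoprotein genes 2 rose, Mttp, the microsomal triglyceride transfer protein (log2 0.71 ± 0.12, edgeR adjusted p = 0.00836), and Sar1b, a secretory GTPase (log2 0.79 ± 0.14, edgeR adjusted p = 0.0108), with 2 higher adjusted over the list alone and a list median of 0.39 (camera adjusted p = 0.0014, adjusted p = 0.241 with an estimated correlation). Of 28 oxidation and PPAR alpha target genes 7 rose (9 adjusted over the list alone, median 0.47, camera adjusted p = 3.66e-05, adjusted p = 0.363 with an estimated correlation), including Acadvl (log2 0.55 ± 0.10). Of 23 bile acid genes 5 rose (10 adjusted over the list alone, median 0.56, camera adjusted p = 0.000123, adjusted p = 0.241 with an estimated correlation), including Cyp27a1 (log2 0.76 ± 0.12) and the uptake transporter gene Slco1a1 (log2 1.32 ± 0.21). Of 22 drug-metabolising P450 genes 5 rose (7 adjusted over the list alone, median 0.56, camera adjusted p = 0.00013, adjusted p = 0.241 with an estimated correlation), including Cyp2j5 (log2 0.91 ± 0.16) and Cyp2d9 (log2 1.14 ± 0.22). Slco1a1 and Cyp2d9 are also in the list of male-biased liver genes, of which 12 of 22 rose. Of 32 genes of choline, phospholipid and methionine metabolism 2 rose, Selenoi (log2 0.40 ± 0.10) and Dmgdh (log2 0.77 ± 0.20), and 1 fell, Slc44a2, a choline transporter-like gene named after its value was seen, while adjusted over the list alone 6 were higher and 1 lower (median 0.31, camera adjusted p = 0.00364, adjusted p = 0.241 with an estimated correlation). Leaving out single libraries gave, in the order used above, 0, 1, 7, 6, 1 and 5 higher oxidation genes and 2, 2, 6, 3, 3 and 7 higher bile acid genes. It gave 2, 3, 6, 3, 1 and 5 higher P450 genes, 2, 2, 3, 2, 2 and 3 higher lipoprotein genes and 0, 0, 3, 0, 0 and 4 higher choline genes. Acadvl did not pass without CSAA replicate 1 (highest edgeR adjusted p = 0.0593). Cyp2d9 did not pass without CSAA replicates 1 or 2 or CDAA replicate 2 (highest edgeR adjusted p = 0.0706). Selenoi did not pass without CSAA replicates 1, 2 or 3 or CDAA replicates 1, 2 or 3 (highest edgeR adjusted p = 0.101). Dmgdh did not pass without CSAA replicates 1, 2 or 3 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.139). The other passing members, Cyp2c70, Slc27a5 and Slc10a1 of the bile acid list and Cyp2a12, Cyp2c29 and Cyp2d10 of the P450 list, were named after their values were seen. Without CDAA replicate 3, 1 oxidation gene and 2 P450 genes were called lower, and without CDAA replicate 1, 1 lipoprotein gene was.

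Lipid uptake and glucose genes split by direction. Of 17 uptake and binding genes 3 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.26, camera adjusted p = 0.217). Lpl, lipoprotein lipase, fell from 149.9 ± 40.2 to 42.4 ± 14.3 CPM (log2 -1.82 ± 0.28, edgeR adjusted p = 0.00614). Fabp7 had a log2 fold change of -1.44 ± 0.24. Lpl and Cd36 are also in the lipid-associated macrophage list, of which 15 of 20 members fell. In the same libraries 18 of 20 monocyte and macrophage markers fell (median -1.79), and the cells behind the falls in uptake and glucose genes were not tested. Of 23 glucose genes 3 rose and 4 fell (6 and 4 adjusted over the list alone, median 0.36, camera adjusted p = 0.169). Among those that fell were the glycolytic enzyme genes Pkm at log2 -1.52 ± 0.16 (edgeR adjusted p = 0.00171) and Hk3 at -1.80 ± 0.24 (edgeR adjusted p = 0.00371). On library size only the median of the uptake list was -0.02. With single libraries left out, 0, 0, 4, 3, 2 and 2 uptake genes were higher and 2, 2, 2, 2, 2 and 3 lower in the order used above. The same fits gave 0, 0, 1, 0, 0 and 6 higher and 2, 4, 2, 4, 2 and 4 lower glucose genes. Named after their values were seen, the other passing members were Fabp1, Slc27a5 and Lipc (higher) and Cd36 (log2 -1.24, lower) of the uptake list, and Pklr and Slc37a4 (higher) and Hk1 and Hk2 (lower) of the glucose list. Pck1 was the third glucose gene that rose.

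Extracellular matrix genes were lower in the libraries labelled CDAA. Of 37 genes 27 fell and 0 rose (28 lower adjusted over the list alone, median log2 -1.11, camera adjusted p = 3.94e-19, adjusted p = 0.219 with an estimated correlation). Besides Mmp12, Col5a1, a fibrillar collagen chain, fell from 38.7 ± 4.17 to 16.5 ± 1.64 CPM (log2 -1.23 ± 0.13, edgeR adjusted p = 0.00155). Of 20 stellate cell and fibroblast markers 9 fell (12 adjusted over the list alone, median -0.68, camera adjusted p = 0.000164, adjusted p = 0.246 with an estimated correlation), including Col1a1, from 126.1 ± 41.6 to 26.3 ± 10.6 CPM (log2 -2.26 ± 0.33, edgeR adjusted p = 0.00483), and the growth factor receptor gene Pdgfrb (log2 -1.29 ± 0.20). Without single libraries, 14, 20, 20, 29, 15 and 22 matrix genes and 4, 5, 7, 7, 4 and 6 stellate cell markers were lower in the order used above. Mmp12, Col5a1, Col1a1 and Pdgfrb passed in all 6 fits.

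Most inflammatory mediators and monocyte and macrophage markers were also lower in the libraries labelled CDAA. Of 33 genes of cytokines, chemokines and their receptors 26 fell (29 adjusted over the list alone, median -2.14, camera adjusted p = 4.75e-37, adjusted p = 0.0884 with an estimated correlation). Ccl5, a T cell and monocyte attractant, fell from 19.1 ± 5.09 to 1.25 ± 0.337 CPM (log2 -3.92 ± 0.29, edgeR adjusted p = 0.00121). Il1rn, the interleukin-1 receptor antagonist, had a log2 fold change of -3.59 ± 0.28. Of 20 monocyte and macrophage markers 18 fell (19 adjusted over the list alone, median -1.79, camera adjusted p = 1.24e-26, adjusted p = 0.0884 with an estimated correlation), including the chemokine receptor genes Cx3cr1 (log2 -3.73 ± 0.33) and Ccr2 (log2 -2.21 ± 0.20). Of 20 lipid-associated macrophage genes 15 fell (15 adjusted over the list alone, median -1.19, camera adjusted p = 1.02e-15, adjusted p = 0.199 with an estimated correlation), including Mmp12 and the integrin gene Itgax (log2 -3.70 ± 0.36). Of 19 neutrophil markers in the files only 4 passed the count filter, among them Lcn2, which is also in the acute phase list. Of these 4 tested markers 3 fell (4 adjusted over the list alone, median -2.18, camera adjusted p = 3.76e-05, adjusted p = 0.219 with an estimated correlation), with Lcn2 and the receptor gene Csf3r (log2 -1.88 ± 0.28) having the smallest adjusted p. Of 14 Kupffer cell markers 4 fell and 1 rose (5 and 1 adjusted over the list alone, median -0.55, camera adjusted p = 0.0281, adjusted p = 0.497 with an estimated correlation), with Cd5l at log2 -1.27 ± 0.19 and Clec1b at -1.07 ± 0.14. The Kupffer cell list did not pass camera without CSAA replicate 3 (adjusted p = 0.443), CDAA replicate 1 (adjusted p = 0.0559) or CDAA replicate 2 (adjusted p = 0.0532), in a range of 0.00233 to 0.443 over the 6 fits. Those fits gave, in the order used above, 21, 25, 23, 24, 23 and 25 lower cytokine genes and 15, 17, 18, 18, 17 and 18 lower monocyte markers. They gave 2, 3, 2, 3, 2 and 3 lower neutrophil markers and 2, 4, 3, 3, 2 and 4 lower Kupffer markers, while 11 to 16 lipid-associated macrophage genes were lower. Other passing members, named after their values were seen, were S100a9 of the neutrophil list, Marco and Id3 (lower) and Paqr9 (higher) of the Kupffer list. Higher Kupffer markers numbered 0, 0, 2, 0, 0 and 1 in those fits.

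Lymphocyte and dendritic cell lists had negative medians as well. Of 21 T and NK cell markers 13 fell (19 adjusted over the list alone, median -1.93, camera adjusted p = 2.88e-12, adjusted p = 0.199 with an estimated correlation). Cd8a, a co-receptor of cytotoxic T cells, fell from 9.73 ± 2.26 to 0.781 ± 0.251 CPM (log2 -3.62 ± 0.32, edgeR adjusted p = 0.00123). Nkg7, a cytotoxic granule protein, had a log2 fold change of -3.56 ± 0.34. Of 18 dendritic cell markers 12 fell (13 adjusted over the list alone, median -1.88, camera adjusted p = 2.41e-13, adjusted p = 0.114 with an estimated correlation), with the MHC class II genes H2-Ab1 (143.3 ± 11.8 to 34.7 ± 10.3 CPM, log2 -2.04 ± 0.20) and H2-Aa (log2 -1.99 ± 0.20). Of 13 B and plasma cell markers 3 fell (5 adjusted over the list alone, median -0.88, camera adjusted p = 0.00217, adjusted p = 0.241 with an estimated correlation), including Blnk (log2 -2.25 ± 0.23) and Cd22 (log2 -1.61 ± 0.29). With single libraries left out in the order used above, 5, 8, 6, 7, 7 and 12 T and NK cell markers were lower. The same fits gave 6, 9, 10, 9, 9 and 10 lower dendritic cell markers and 1, 3, 2, 2, 2 and 2 lower B cell markers. Cd22 did not pass without CSAA replicate 1 (highest edgeR adjusted p = 0.0538). Cd8a, Nkg7, H2-Ab1, H2-Aa and Blnk passed in all 6 fits. Ms4a1, the third B cell marker that fell, was named after its value was seen.

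**Figure D4:**
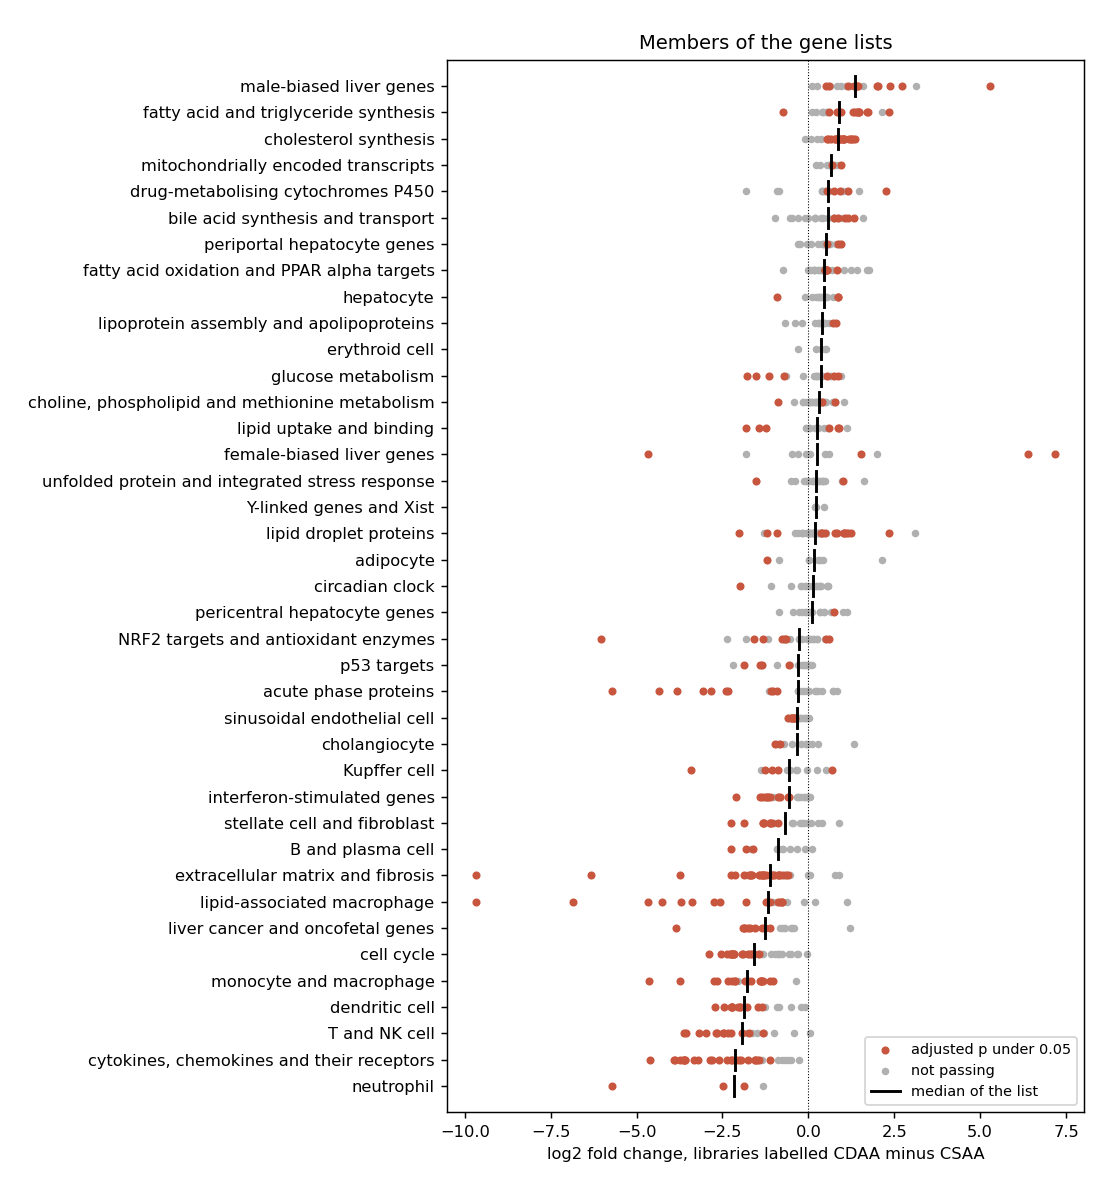
Log2 fold change (libraries labelled CDAA minus CSAA) of each tested member of the 39 gene lists with at least 3 tested members, red at an edgeR adjusted p under 0.05 and grey otherwise, with the list median as a black bar. Medians run from 1.34 for male-biased genes to -2.18 for neutrophil markers, of which only 4 of 19 were tested.

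Among proliferation, interferon, acute phase, oncofetal and p53 target genes, those that passed with all 6 libraries were lower in the libraries labelled CDAA. Of 33 cell cycle genes 17 fell (28 adjusted over the list alone, median -1.57, camera adjusted p = 1.97e-13, adjusted p = 0.199 with an estimated correlation), including the mitotic genes Cenpe (8.86 ± 2.72 to 1.18 ± 0.256 CPM, log2 -2.90 ± 0.33) and Bub1b (log2 -2.16 ± 0.28). Of 26 interferon-stimulated genes 11 fell (16 adjusted over the list alone, median -0.57, camera adjusted p = 1.88e-07, adjusted p = 0.219 with an estimated correlation), including the guanylate-binding protein genes Gbp2 (log2 -2.09 ± 0.18) and Gbp3 (log2 -1.27 ± 0.14). Of 24 acute phase genes 10 fell and 0 rose (11 lower and 3 higher adjusted over the list alone, median -0.31, camera adjusted p = 0.000191, adjusted p = 0.363 with an estimated correlation), including Lcn2 and the orosomucoid gene Orm2 (log2 -4.35 ± 0.42). Of 19 liver cancer and oncofetal genes 10 fell (11 adjusted over the list alone, median -1.27, camera adjusted p = 1.38e-09, adjusted p = 0.219 with an estimated correlation), including S100a11 (log2 -1.88 ± 0.18) and the annexin gene Anxa5 (log2 -1.35 ± 0.15). Of 17 p53 targets 4 fell (5 adjusted over the list alone, median -0.29, camera adjusted p = 0.0108, adjusted p = 0.354 with an estimated correlation), including Plk2 (log2 -1.42 ± 0.21) and Pmaip1 (log2 -1.34 ± 0.30). The p53 list did not pass camera without CSAA replicate 2 (adjusted p = 0.0584, in a range of 0.00161 to 0.0584 over the 6 fits). Pmaip1 did not pass without CSAA replicates 1, 2 or 3 or CDAA replicate 1 (highest edgeR adjusted p = 0.0845). Without single libraries, in the order used above, 9, 17, 13, 10, 9 and 23 cell cycle genes and 6, 6, 6, 8, 7 and 15 interferon-stimulated genes were lower. The same fits gave 1, 1, 1, 3, 2 and 4 lower p53 targets, 8 to 10 lower acute phase genes and 8 to 11 lower oncofetal genes. Without CSAA replicate 3, 4 acute phase genes were called higher, against 0 with all 6 libraries. Phlda3 and Zmat3, the other p53 targets that fell, were named after their values were seen.

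With the settings stated at the start and all 6 libraries, stress response lists did not pass camera as sets. Of 26 NRF2 targets and antioxidant genes 6 fell and 2 rose (6 and 3 adjusted over the list alone, median -0.28, camera adjusted p = 0.0647), the fallers including Slc7a11, the cystine transporter (6.94 ± 5.23 to 0.0981 ± 0.0851 CPM, edgeR adjusted p = 0.00468), and heme oxygenase Hmox1 (log2 -1.58 ± 0.22). Of 23 unfolded protein and integrated stress genes 1 rose, Herpud1 (log2 1.01 ± 0.28), and 1 fell, Atf3 (log2 -1.54 ± 0.41), with 0 passing adjusted over the list alone (median 0.22, camera adjusted p = 0.0953). Herpud1 did not pass without CSAA replicates 1 or 3 or CDAA replicates 1, 2 or 3 (highest edgeR adjusted p = 0.154). Atf3 did not pass without CSAA replicates 1 or 2 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.15). The NRF2 list passed camera without CSAA replicate 1 (adjusted p = 0.0397), CSAA replicate 3 (adjusted p = 0.0268) or CDAA replicate 3 (adjusted p = 3.2e-05), in a range of 3.2e-05 to 0.182 over the 6 fits. The unfolded protein list passed as higher without CSAA replicate 2 (adjusted p = 0.0304) or CDAA replicate 2 (adjusted p = 0.00478). On library size only its median was -0.05, and it passed camera, which sets a list against the other genes (camera adjusted p = 0.024). Leaving out single libraries gave 2, 4, 4, 4, 3 and 12 lower and 0, 2, 1, 1, 0 and 1 higher NRF2 targets in the order used above. Gstp1 and Sod1, the NRF2 list members that rose, were named after their values were seen. Slc7a11 was at 12.8 CPM in CSAA replicate 1 and at 2.88 and 5.10 in CSAA replicates 2 and 3, and its log2 fold change was -6.04 ± 0.87, or -5.21 without CSAA replicate 1.

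Male-biased liver genes were higher in the libraries labelled CDAA, although all 6 libraries expressed Y-linked genes. Of 22 genes 12 rose (17 adjusted over the list alone, median 1.34, camera adjusted p = 5.02e-11, adjusted p = 0.219 with an estimated correlation), including the fatty acid elongase gene Elovl3, from 101.9 ± 41.4 to 418.3 ± 88.5 CPM (log2 2.04 ± 0.31, edgeR adjusted p = 0.00592), and Slco1a1. Single libraries left out, in the order used above, gave 3, 5, 10, 7, 6 and 15 higher male-biased genes. Of 12 female-biased genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.0953). The female-biased genes that rose included Cyp2c40 and Cyp2c69, the latter at 0.0414 ± 0.0718 CPM in CSAA and 6.48 ± 4.74 CPM in CDAA, and the list's median was -0.26 without CDAA replicate 3 and -0.01 on library size only. The female-biased list passed as higher without CDAA replicate 1 (adjusted p = 0.0212) or CDAA replicate 2 (adjusted p = 0.00508). On library size only it also passed camera against the other genes (camera adjusted p = 0.00176). The third female-biased gene that rose was Cyp17a1, named after its value was seen, and the gene that fell was Atp6v0d2. Cyp2c69 was at 0.124 CPM in CSAA replicate 3 and at 0 in CSAA replicates 1 and 2, and in CDAA at 11.7 CPM in replicate 3 and at 5.18 and 2.52 in replicates 1 and 2.

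Few hepatocyte, zonation and mitochondrial genes passed. Of 20 hepatocyte markers 2 rose, Cps1 (log2 0.85 ± 0.18) and Serpina1c (log2 0.87 ± 0.23), and 1 fell, the hemopexin gene Hpx, named after its value was seen (5 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 0.000421, adjusted p = 0.358 with an estimated correlation). Of 18 periportal genes 3 rose, including Cps1 and Pck1 (log2 0.55 ± 0.13), with 8 adjusted over the list alone (median 0.51, camera adjusted p = 0.000191, adjusted p = 0.241 with an estimated correlation). Of 17 pericentral genes 1 rose, Cyp27a1, also 1 adjusted over the list alone (median 0.10, camera adjusted p = 0.0725), and on library size only that median was -0.19. The pericentral list passed as higher without CSAA replicate 2 (adjusted p = 0.00837) or CDAA replicate 3 (adjusted p = 0.00828). On library size only it also passed camera against the other genes (camera adjusted p = 0.0148). Its median turned to -0.01 without CDAA replicate 1 and to -0.05 without CDAA replicate 2. Of 12 mitochondrially encoded genes 2 rose, mt-Nd6 (log2 0.96 ± 0.22) and mt-Nd2 (log2 0.69 ± 0.18), with 7 adjusted over the list alone (median 0.65, camera adjusted p = 4.77e-05, adjusted p = 0.354 with an estimated correlation). Single libraries left out gave, in the order used above, 0, 0, 4, 0, 0 and 5 higher hepatocyte markers, 0, 0, 6, 1, 0 and 6 higher periportal genes and 1, 0, 6, 0, 0 and 1 higher mitochondrial genes. Cps1 and Serpina1c did not pass without CSAA replicates 1 or 2 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.0842 and 0.152). Pck1 did not pass without CSAA replicates 1, 2 or 3 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.0961). mt-Nd6 did not pass without CSAA replicate 2 or CDAA replicates 1 or 2 (highest edgeR adjusted p = 0.069). mt-Nd2 did not pass without CSAA replicates 1 or 2 or CDAA replicates 1, 2 or 3 (highest edgeR adjusted p = 0.127). Etnppl, the third periportal gene that rose, was named after its value was seen. Without CDAA replicate 3, 2 periportal genes were called lower.

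Of the remaining lists only that of sinusoidal endothelial markers passed camera with the settings stated at the start and all 6 libraries. Of 18 sinusoidal endothelial markers 7 fell (8 adjusted over the list alone, median -0.33, camera adjusted p = 0.00519, adjusted p = 0.241 with an estimated correlation), including Eng (log2 -0.50 ± 0.09) and Pecam1 (log2 -0.59 ± 0.11), and single libraries left out gave 0, 1, 4, 4, 2 and 7 in the order used above. Of 14 cholangiocyte markers 2 fell, Spp1 (log2 -0.83 ± 0.19) and Ezr (log2 -0.97 ± 0.27), also 2 adjusted over the list alone (median -0.34, camera adjusted p = 0.591). Spp1 is also in the lipid-associated macrophage and matrix lists. The cholangiocyte median turned to 0.20 without CSAA replicate 1. Of 8 adipocyte markers 1 fell, Cidec, also 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.62). Of 18 circadian clock genes 1 fell, Bhlhe41 (log2 -1.99 ± 0.51), with 0 adjusted over the list alone (median 0.14, mean -0.04, camera adjusted p = 0.304). Eng did not pass without CSAA replicate 1 (highest edgeR adjusted p = 0.0537). Pecam1 did not pass without CSAA replicates 1 or 2 (highest edgeR adjusted p = 0.0648). Spp1 did not pass without CSAA replicates 1, 2 or 3 or CDAA replicate 2 (highest edgeR adjusted p = 0.108). Ezr and Bhlhe41 did not pass without CSAA replicates 1, 2 or 3 or CDAA replicates 2 or 3 (highest edgeR adjusted p = 0.177 and 0.152). Cidec did not pass without CSAA replicates 1 or 2 or CDAA replicates 1, 2 or 3 (highest edgeR adjusted p = 0.126). On library size only the adipocyte median was -0.12, the clock median -0.15 and the Y-linked median -0.06. The adipocyte list passed as higher without CDAA replicate 3 (adjusted p = 0.0249) and the erythroid list without CSAA replicate 3 (adjusted p = 0.00452). Of 5 erythroid markers 0 passed (median 0.37, camera adjusted p = 0.183), with Alas2 at log2 0.51 ± 0.27 and Hbb-bt at 0.48 ± 0.27, and of 4 Y-linked genes 0 passed over all genes and 1 adjusted over the list alone (median 0.21, camera adjusted p = 0.1). Only 1 pancreatic acinar gene, Cela1 (edgeR adjusted p = 0.11), and 1 striated muscle gene, Mylpf (edgeR adjusted p = 0.12), entered the test with all 6 libraries, and neither passed. Without CDAA replicate 3, 2 acinar genes were called higher. Without CDAA replicate 1 the log2 fold change of Cela1 was 0.36 (edgeR adjusted p = 0.703) and that of Mylpf 0.27 (edgeR adjusted p = 0.768), against 3.23 and 2.80 with all 6 libraries. Without CDAA replicate 3, 3 adipocyte markers were called higher, and without CSAA replicate 3, 2 erythroid markers were.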

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

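The tests in this part were chosen after the result was seen. Transcripts of the pancreas and of striated muscle, mostly outside the tested genes, stood out in a single library. In CDAA replicate 1 the 18 pancreatic acinar genes summed to 2135.8 CPM (0.214% of its reads) and the 12 striated muscle genes to 280.37 CPM (0.028%), against at most 16.9 and 1.61 CPM in the other 5 libraries, those labelled CSAA included. The most abundant acinar transcripts were Ctrb1 at 275.4, Pnlip at 270.2 and Cpa1 at 202.0 CPM, and the most abundant muscle transcript was Acta1 at 73.9 CPM, on unscaled totals. Expression of these genes by liver on the diet is argued against, since at most 1 acinar gene reached 1 CPM in another library labelled CDAA. A candidate explanation is carried-over tissue: 17 of the 18 acinar genes and 11 of the 12 muscle genes reached 1 CPM in that library, against at most 3 and 0 in any other. Some adipocyte genes were also highest there: 11 of 14 reached 1 CPM, against 8 in each other library, with Plin1 at 4.53, Cfd at 3.09 and Adipoq at 2.67 CPM, against at most 0.981 in any other. The next highest library for each was CDAA replicate 2 (0.654, 0.981 and 0.458 CPM), with at most 0.176 CPM in the remaining libraries. Plin1 is in the lipid droplet list but was not among its tested members. The source of the adipocyte transcripts was not tested. Whether the tissue came in at dissection or later was not tested. Without the genes of both lists 542 genes were higher and 1352 lower, with 1894 of the 1901 calls shared. That fit could change little, since of both lists only Cela1 and Mylpf were tested. It also leaves in any other transcripts of those tissues. Without CDAA replicate 1, 1070 of the 1901 calls were shared, against 863 without CDAA replicate 2 and 1581 without CDAA replicate 3. The effect of the carried-over transcripts on the calls thus stays open.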

How the results depend on the processing

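Thinning and leaving out the pancreatic and muscle genes were chosen after the data were seen, and the other alternatives before. 0 of the 1901 called genes changed sign in any of these fits, and 1866 of the calls were shared with RLE factors, 1887 with DESeq2 and 1823 after thinning. A change of sign was unlikely from the start, since 1898 of the called genes had no overlap between the groups. Counts moved by over 1.5 times as follows, with the cause not tested except where a stricter threshold explains it. Having fewer libraries does not account for every move. Genes at least 2-fold higher numbered 97 with all 6 libraries and 159 without CDAA replicate 3, and were fewer than 97 with any other library left out. With library size only, 137 genes were higher and 2745 lower (57 and 1477 at least 2-fold), 5 lipid droplet members were higher and 6 lower, and 8 list medians turned, to -0.0938 (lipid droplet), -0.0492 (unfolded protein), -0.0116 (female-biased), -0.19 (pericentral), -0.0182 (lipid uptake), -0.15 (circadian clock), -0.12 (adipocyte) and -0.0632 (Y-linked). The female-biased median was also -0.18 with limma-voom. DESeq2 called 1103 genes higher (151 at least 2-fold). At an adjusted p under 0.01, 46 were higher and 531 lower (22 and 468 at least 2-fold), 3 and 0 lipid droplet members remained, and 47 of the 79 genes chosen by the naming rule passed. With single libraries left out, genes higher ran from 76 to 688 and lower from 568 to 1456, at least 2-fold from 26 to 159 and from 482 to 1010, lipid droplet members higher from 4 to 13 and lower from 1 to 3, and genes of the naming rule from 52 to 73. With an estimated correlation 0 of 28 list calls held (lipid droplet median 0.19, adjusted p = 0.219), and 22 held with fry.

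The labels do not say whether shared replicate numbers pair the mice. Deviations of same-numbered libraries correlated at 0.07, 0.12 and -0.06, and 3 of 6 libraries correlated best with their own number. With 3 libraries per group these values cannot decide whether a pairing or a shared batch exists. With the replicate block 293 genes were higher and 1090 lower, 1 lipid droplet member was lower, and the female-biased median was -0.17.

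Thinning to the lowest total, 14580676 reads from at most 17367173, gave 541 higher and 1342 lower and says little about depth. At the real depth and 3 libraries per group, 33 of 67 simulated genes with a 2-fold change were recovered and 2 of 67 with a 1.5-fold change. That simulation changed 200 of 12845 genes, a smaller share than was called in the libraries, so its recovery can differ from theirs.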

Other observations

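The lists and tests in this part were chosen after the data were seen, except the count over other splits of the libraries. Of 11 heat shock genes, which encode cytosolic chaperones and the mitochondrial Hspd1 and Hspe1, 8 rose in the libraries labelled CDAA, Hspd1 and Hspe1 among them, and 0 fell (median log2 0.57). Hspa1b rose from 26.5 ± 5.98 to 123.8 ± 76.3 CPM (log2 2.22 ± 0.43, n = 3 each, edgeR adjusted p = 0.0141) and Hsph1 from 61.3 ± 6.19 to 131.6 ± 37.1 CPM. Of 19 genes of the actin cytoskeleton and tubulins 9 fell (median -0.47). The largest falls in this list were in Capg (log2 -3.06 ± 0.33), Coro1a (log2 -2.34 ± 0.18) and Tmsb10 (log2 -1.49 ± 0.20). Of its 7 tested tubulin genes only Tubb6 passed (log2 -1.33 ± 0.15), and Tubb5, Tuba1b, Tubb4b, Tuba1c, Tubb2a and Tuba1a did not. Of 9 tested genes of T cell activation and exhaustion 6 fell (median -2.01, also -2.01 with Tigit, at 0 counts in CDAA, set at its bound), among them Cd274, the ligand PD-L1, from 10.3 ± 1.91 to 2.54 ± 0.522 CPM. Of 26 lysosomal genes 9 fell (median -0.25), including Laptm5 (log2 -1.90 ± 0.16) and Ctss (log2 -2.18 ± 0.25), while Gaa, Lamp2 and Npc1 had fold changes above 0 that did not pass. Actb, Actg1, Lamp1 and Ctsl did not pass either, and 18 of 20 monocyte and macrophage markers fell in the same libraries (median -1.79). Genes were put into these 4 lists after their values were seen, so the counts describe the libraries and no set test is given.

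CDAA replicate 3 was set against the mean of CDAA replicates 1 and 2 by the median log2 difference of each list. The lists with a difference beyond 0.4 either way were female-biased genes (1.27), male-biased genes (-0.88), adipocyte markers (-0.64), cell cycle genes (0.61), pericentral genes (-0.49), fatty acid and triglyceride synthesis (-0.49), NRF2 targets (0.47), stellate cell markers (-0.42) and matrix genes (-0.41). Between CDAA replicates 1 and 2 the matrix genes differed by 0.63, the male-biased genes by 0.58 and the female-biased genes by -0.58. Over genes with a mean of at least 10 CPM, 258 differed by more than 2-fold from that mean, against 123 between CDAA replicates 1 and 2.

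Macrophage, cytokine and matrix genes were lower, and lipid synthesis genes higher, in the libraries labelled CDAA, whereas choline-deficient feeding is commonly used to bring about liver inflammation and fibrosis. Scaling is argued against as the whole cause, since the monocyte and macrophage median stayed at -1.77 or below under all 4 scalings, and so is a smaller hepatocyte share in CSAA by itself, since the median of that list was 1.46 log2 units lower (-1.465) than that of the sinusoidal endothelial list (permutation over genes p = 0.00014, genes not being independent replicates). For a single wrongly labelled library the measures differ. All 6 libraries correlated best with their own group, which argues against it. By the chi-square statistic per degree of freedom, CDAA replicate 3 lay nearer to CSAA replicate 3 (54.16) than to CDAA replicate 2 (61.93) or replicate 1 (81.85). For CDAA replicate 3 the question thus stays open. An exchange of both diet labels for all 6 libraries cannot be told apart from a response in the stated direction: it would turn the median of -1.79 to the same size with the other sign, and no transcript marks the feed independently of the response. Both may be considered, and the biological difference in diet stays open as untested.

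Of the 10 splits of the 6 libraries into 3 and 3, only the split by label called as many as 1901 genes (1 of 10), and the highest other split called 1 gene. With 10 splits the share cannot fall under 0.1.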
